A study of Mus musculus with 20 samples.

How the data were processed

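Kidney RNA of 20 libraries in 4 groups of 5 (wild type and ARLmon mice, each with vehicle or testosterone for 4 days after orchidectomy) had been prepared with a stranded poly(A) kit and sequenced on an Illumina instrument. The authors name FastQC 0.11.7, HISAT2, SAMtools 1.5, HTSeq 2.7.14 (as they list it), DESeq2 and the mm10 build, without settings, annotation or the strand setting of the counting. They deposited 4 tables of counts, each for a pair of groups, with whole-number raw counts per gene for 10 libraries. They also deposited a table of log2 values for 20550 genes in all 20 libraries, exported from Qlucore, whose normalization is not stated. The values show that the count tables are not normalized and that genes with fewer than 2 counts over the 10 libraries of a pair are absent.

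The count tables held the same values wherever they shared a library, so they were joined into 1 table of 24762 genes by 20 libraries. Where a gene was absent from the table that held a library, 12045 values in 1713 genes were set to 0, which can leave out at most 1 read per pair table. Each column carries a library code that gives its group but not the replicate number of the labels. All columns were assigned to a group. Total counts ran from 8342000 to 38101526 per library. Between libraries of one group, the chi-square per degree of freedom over genes with at least 10 reads ran from 5.23 to 139, and Spearman's correlation from 0.964 to 0.994, so no 2 libraries of one group were copies of each other. Across 14698 genes in both kinds of table, the median correlation of log2 CPM with the log2 table over the libraries was 0.949, and 294 genes (2.00%) were below 0.5.

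Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood fit with 4 group means, 16 residual degrees of freedom), which left 15549 genes tested. A gene was called changed or different at a Benjamini-Hochberg adjusted p below 0.05. SE values are the size of the log2 change over the square root of the F statistic. The contrasts were testosterone minus vehicle in each genotype, ARLmon minus wild type under each treatment, ARLmon testosterone minus wild type vehicle, and the difference of the 2 testosterone effects. The slope of the ARLmon response on the wild type response was fitted through the origin over genes called in wild type. The comparisons, the tests, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined.

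Named genes are Kap and Odc1 in every comparison, and results for some other genes are not reported here. In the wild type testosterone comparison and the comparison of genotypes under testosterone they include the 8 largest rises and falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. In the other comparisons they are the 5 largest each way, for the interaction without the criterion on overlap, and of each gene list up to 4 members with the smallest p and members that go against it. Predicted and unnamed genes are counted only. Where a group had 0 reads of a gene, a floor of 3 reads over the group gives a bound on the fold, and with 1 to 3 reads the ratio is given with its 95% counting interval. Positions are those of GENCODE M21 on GRCm38, which need not be the annotation the authors used, and 14799 (95.2%) of the tested genes matched it by symbol.

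The 36 gene lists of pathways and of kidney and other cell types were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided and adjusted over the 35 lists with at least 5 tested members. The other list, of adrenal gland genes, was not tested. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move, on balance, in one direction, without comparing them with other genes.

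Alternatives were median-ratio (RLE) factors, library size as the only scaling, no filter or a stricter one (1 CPM in 5 libraries), DESeq2 1.42.0, limma-voom, a minimum log2 change of 1, the 10 most abundant genes left out, the 10 libraries of a pair alone, and each library left out in turn. After the data were seen, fits without 2 libraries, with a covariate for the main axis of variation within groups, and of limma on the deposited log2 values were added. Each count was set beside those of 100 splits of the libraries into groups of the same sizes. Figures were drawn with matplotlib 3.10.9.

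The test was checked on simulated counts with the means, sizes and spread of the real libraries. It recovered 43.3%, 85.1% and 97.0% of 1.5-, 2- and 4-fold changes in wild type and 38.8%, 80.6% and 92.4% in ARLmon, and a simulated slope of 0.5 was estimated as 0.490.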

Results

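Gene expression was measured by poly(A) RNA sequencing in 20 kidney libraries from male mice that were orchidectomised and then received testosterone or vehicle for 4 days. Wild type C57BL/6J mice were set beside ARLmon/Y mice under the same treatments. The 4 groups held 5 libraries each. Reads assigned to genes numbered 18915960, 19501503, 25506705, 38101526 and 8618311 in the wild type vehicle libraries GC078602 to GC078606, in that order. The wild type testosterone libraries GC078607 to GC078611 held 8474585, 8845274, 8342000, 15422018 and 11154979. The ARLmon testosterone libraries GC078612 to GC078616 held 10236738, 15902011, 12517531, 18609328 and 14978740, and the ARLmon vehicle libraries GC078617 to GC078621 held 12440144, 11569255, 14375849, 16207120 and 16881304. Between 18781 and 21719 genes were detected per library. The labels do not say whether each library came from a separate animal, so every p measures the spread between these samples. Intervals and floors given for low read counts cover counting error only.

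On the first principal component, which held 41.4% of the variance, the wild type testosterone libraries lay between -61.3 and -49.4 and the wild type vehicle libraries between -16.4 and 12.8. The ARLmon libraries lay between 26.5 and 43.8 with vehicle and between 7.22 and 37.7 with testosterone. Mitochondrial genes took 6.86% to 11.1% of the counts per library.

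**Figure D1:**
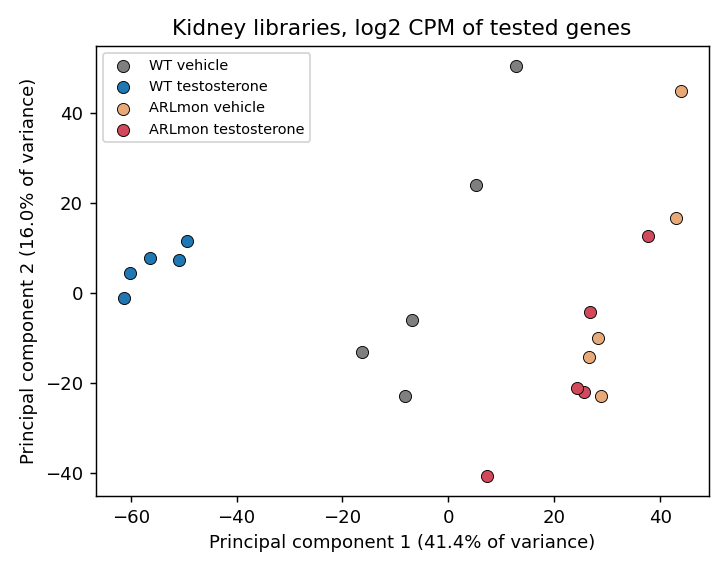
Scores of the 20 libraries on principal components 1 and 2 of log2 CPM, with 1 point per library and a colour for each of the 4 groups. The wild type testosterone libraries sit apart, between -61.3 and -49.4 on component 1, while the ARLmon groups overlap.

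The first comparison asked which genes testosterone changes in wild type kidneys. The organic anion transporter gene Slco1a1 (chromosome 6, 141907282 to 141946962, GRCm38) went from 19.5 ± 3.14 CPM (read counts scaled by library size and TMM factor; mean ± SD, n = 5 per group here and throughout) with vehicle to 1431 ± 274 with testosterone, a log2 rise of 6.20 ± 0.23 (SE here and throughout; edgeR adjusted p = 6.2e-14). Odc1 (chromosome 12, 17544794 to 17551505), which encodes the first enzyme of polyamine synthesis, rose from 206 ± 32.4 to 1509.7 ± 119 CPM (log2 2.87 ± 0.12, adjusted p = 9.15e-13). The kidney androgen-regulated protein gene Kap (chromosome 6, 133849851 to 133853762) rose from 14797 ± 7845 to 39464 ± 5353 CPM (log2 1.42 ± 0.32, adjusted p = 0.00329). Prlr (chromosome 15, 10177238 to 10349180), which encodes the prolactin receptor, went from 77.7 ± 37.1 to 5.23 ± 1.13 CPM (log2 -3.89 ± 0.31), and Kynu (chromosome 2, 43555329 to 43682715), which encodes the tryptophan-degrading enzyme kynureninase, from 30.1 ± 3.06 to 3.11 ± 1.16 (log2 -3.32 ± 0.18). Both fell.

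**Figure D2:**
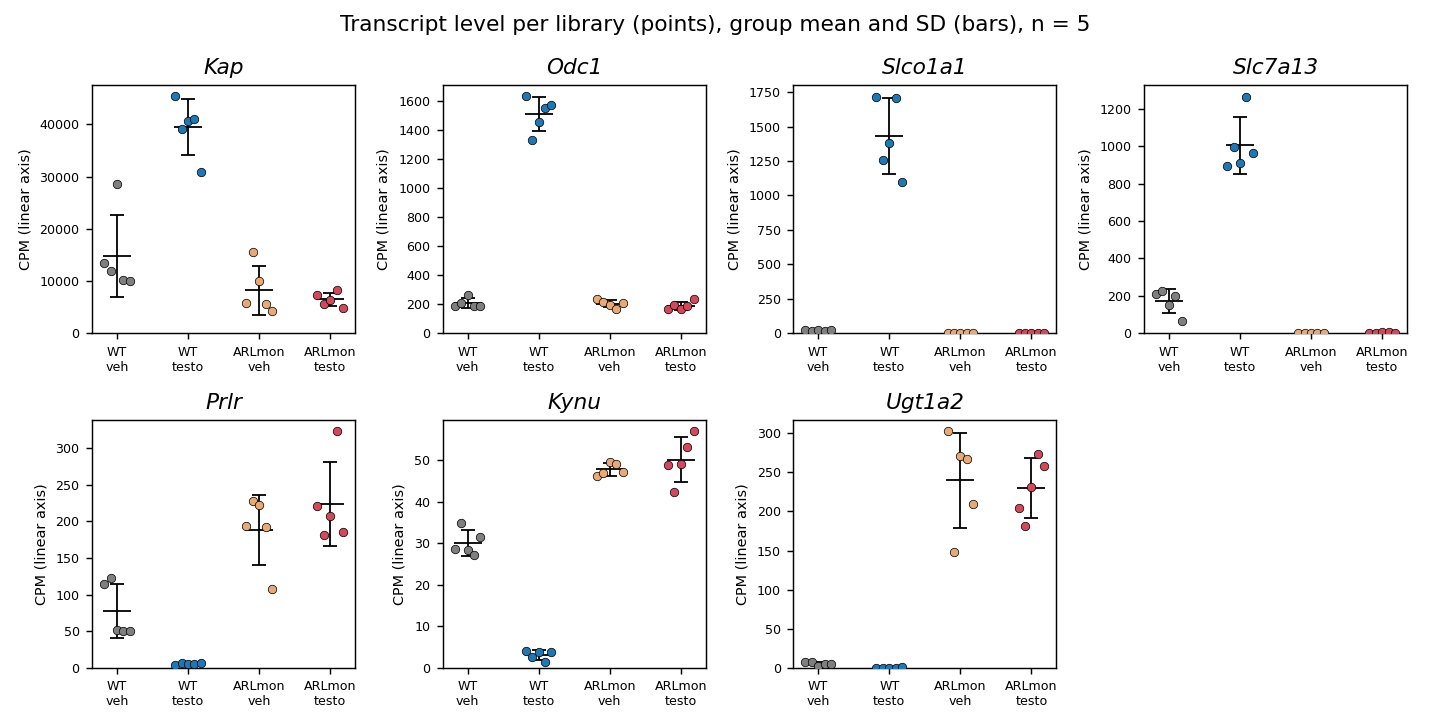
Level in CPM of Kap, Odc1, Slco1a1, Slc7a13, Prlr, Kynu and Ugt1a2 in each library of the 4 groups, with points for libraries and bars for the mean and SD of 5. Slco1a1 averages 1431 CPM in wild type testosterone kidneys and 0.348 in ARLmon testosterone kidneys.

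Among the other largest rises, Synpr, which encodes a synaptic vesicle protein, had 3 reads over the 5 vehicle libraries and averaged 9.69 CPM with testosterone, a ratio of 355 with a lower 95% counting limit of 121 (ratio 232, limit 79.5 without GC078605). The log2 rise was 5.79 ± 0.33 for Cntnap5a, 5.38 ± 0.27 for Ctxn3, 5.05 ± 0.47 for Lipo2 and 4.78 ± 0.36 for Rnf180. The chemokine gene Ccl28 rose by 4.62 ± 0.39, from 3.80 to 95.4 CPM, and Angptl7 by 4.39 ± 0.25. Among the largest falls, the glucuronosyltransferase gene Ugt1a2 (chromosome 1, 88200601 to 88218997) changed by -4.38 ± 0.49, the fibrinogen chain genes Fgb and Fgg by -4.24 ± 0.96 and -3.55 ± 0.70, and Kcnip2 by -3.40 ± 0.32. Gc, which encodes the vitamin D-binding protein, changed by -3.25 ± 0.36 and the amino acid transporter gene Slc7a12 by -3.07 ± 0.67. Wild type vehicle library GC078606 lay above the rest of its group for Fgb, Fgg, Gc and Kcnip2. Without it the log2 change was -2.32 for Fgb and -1.76 for Fgg, and without wild type testosterone library GC078611 it was -4.02 for Slc7a12 and -5.13 for Ugt1a2. With limma-voom the adjusted p of Fgb was 0.0567. Reads of Ugt1a2 can be shared with Ugt1a10, which overlaps it on the same strand, and those of Prlr with Gm21973 and of Fgg with the antisense gene Gm30097. The strand setting of the counting was not stated, so these values are uncertain.

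In all, edgeR called 2444 of 15549 tested genes changed in wild type, of which 1455 rose and 989 fell, and 522 changed at least 2-fold. Of these genes, 167 are predicted or unnamed. With a mean of at least 5 CPM in the higher group and no overlap between the groups, which chance gives for 0.794% of genes, there were 1540. DESeq2 called 2765 genes and limma-voom 2268. With library size as the only scaling, the median log2 change of all genes was -0.18, against -0.03, and of the 3584 genes called 897 rose and 2687 fell.

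Of the 20 androgen-induced kidney genes, a list of which 12 members are also in another list, 17 rose, 1 fell and 2 did not pass the test (adjusted over the list alone, 17 rose and 2 fell; camera adjusted p = 1.41e-22, and adjusted p = 6.98e-05 with an estimated correlation). Hsd17b11, a hydroxysteroid dehydrogenase gene, rose by 2.89 ± 0.10 from 141 to 1046 CPM, the acyl-CoA synthetase gene Acsm3 by 3.96 ± 0.25 and the lysosomal glucuronidase gene Gusb by 1.78 ± 0.10. Against the list, the efflux pump gene Abcc4 changed by -1.10 ± 0.18. Of the 12 androgen-lowered kidney genes (7 also in another list), 5 fell and 1 rose (adjusted over the list alone, 6 and 1; camera adjusted p = 0.0011, and adjusted p = 0.18 with an estimated correlation). They include Kynu, Prlr and Hao2 (-2.48 ± 0.25), and Slco1a6 went the other way at 0.78 ± 0.18.

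Of 24 steroid metabolism genes, 10 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.000291, and adjusted p = 0.0591 with an estimated correlation). Hsd11b1, whose enzyme activates glucocorticoids, rose by 2.84 ± 0.17, the steroid reductase genes Srd5a2 and Srd5a1 by 3.41 ± 0.31 and 1.12 ± 0.16, and Ugt2b38 by 2.09 ± 0.17. Hsd17b14 (-1.03 ± 0.28) was among the 3 that fell. In the steroid metabolism list 8 members are also in another list, and Hsd17b11 and Cyp7b1 are also in the androgen-induced list. Of 34 organic anion and cation transporter genes, 14 rose and 7 fell (16 and 7 adjusted over the list alone; camera adjusted p = 0.00693, and adjusted p = 0.649 with an estimated correlation). Slco3a1 (1.48 ± 0.14) and Slc17a3 (1.63 ± 0.17) rose, while Slc22a29 (-2.57 ± 0.22), Abcb1b (-2.45 ± 0.28) and Slc22a8 (-1.80 ± 0.23) fell. Slc22a29 had the opposite sign in the deposited log2 values, at 0.65. Of 27 amino acid transporter genes, 3 rose and 6 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.0462, and adjusted p = 0.649 with an estimated correlation). Slc7a8 (-0.88 ± 0.10), Slc3a2 (-0.98 ± 0.11) and Slc7a7 (-1.10 ± 0.13) fell, while Slc7a13 (chromosome 4, 19818725 to 19842218) rose by 2.56 ± 0.31. This list's call was lost without any one of GC078602, GC078603, GC078605, GC078607, GC078608, GC078610, GC078615 or GC078621, with an adjusted p of up to 0.146 (without GC078605). Of 10 markers of the straight part of the proximal tubule, 4 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.00762, and adjusted p = 0.649 with an estimated correlation). These were Atp11a (459 to 2981 CPM), Slc22a30 (2.47 ± 0.29), Slc7a13 and Cyp7b1 (1.56 ± 0.25), and all but Atp11a are solute carriers or steroid-metabolising enzymes. Of the 10 markers 6 are also in another list, and Slc7a13 and Cyp7b1 are also in the androgen-induced list.

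Of 10 podocyte markers 7 fell (8 adjusted over the list alone; camera adjusted p = 3.19e-05, and adjusted p = 0.252 with an estimated correlation), such as Podxl (-0.51 ± 0.10) and Synpo (-0.54 ± 0.09). Of 10 smooth muscle and renin cell markers 4 fell (8 adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.252 with an estimated correlation), such as Acta2 (-0.73 ± 0.15) and Cnn1 (-0.79 ± 0.20). Vehicle library GC078606 stood highest for this list, and without it the camera adjusted p was 0.00127. Of 12 endothelial markers 2 fell (6 adjusted over the list alone; camera adjusted p = 0.00412, and adjusted p = 0.649 with an estimated correlation), including Eng (-0.50 ± 0.11). Of 14 fibroblast and matrix genes 2 fell (2 adjusted over the list alone; camera adjusted p = 0.0482, and adjusted p = 0.658 with an estimated correlation), including Fbln1 (-0.85 ± 0.14), and of 16 collecting duct markers 1 fell (0 adjusted over the list alone; camera adjusted p = 0.0418, and adjusted p = 0.658 with an estimated correlation). The call of the fibroblast list was lost without any one of GC078602, GC078603, GC078605, GC078606, GC078607, GC078610, GC078611, GC078615 or GC078617 (adjusted p up to 0.189, without GC078611), and that of the collecting duct without GC078604, GC078605, GC078610 or GC078611 (up to 0.119, without GC078604). Of 19 tubular injury genes 5 fell (7 adjusted over the list alone; camera adjusted p = 0.00115, and adjusted p = 0.658 with an estimated correlation), led by the osteopontin gene Spp1 (-1.40 ± 0.26) and by Fgg. Without GC078606 the change of Fga, another of the 5, went from -2.18 to -0.77 and lost its call (adjusted p = 0.141), and the camera adjusted p of the list was 0.00743. The list lay at percentile 100 of random lists along the main axis of variation between libraries of one group.

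Of 32 proliferation genes, 2 rose and 6 fell (2 and 10 adjusted over the list alone; camera adjusted p = 0.00693, and adjusted p = 0.658 with an estimated correlation). Kif20a (-1.23 ± 0.28) and Cdk1 (-1.21 ± 0.29), both at work in mitosis, fell, and the replication licensing gene Mcm6 rose by 0.72 ± 0.11. Testosterone library GC078611 stood lowest for this list, and the camera adjusted p was 0.0428 without it and 0.0688 without GC078604. Of 78 ribosomal protein genes 5 fell (0 adjusted over the list alone; camera adjusted p = 3.05e-07, and adjusted p = 0.658 with an estimated correlation). None of 26 interferon response genes passed the test over all genes or over the list alone, and their median was -0.31 (camera adjusted p = 0.00852, and adjusted p = 0.658 with an estimated correlation; adjusted p = 0.0823 without GC078611). Along the main axis between libraries of one group, ribosomal protein genes lay at percentile 100, interferon response at 97.2 and proliferation at 95.85. Podocyte and endothelial markers, which also fell, lay at 13.85 and 34.3. By camera 15 of 35 lists passed, and 1 did with an estimated correlation, the androgen-induced genes.

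**Figure D3:**
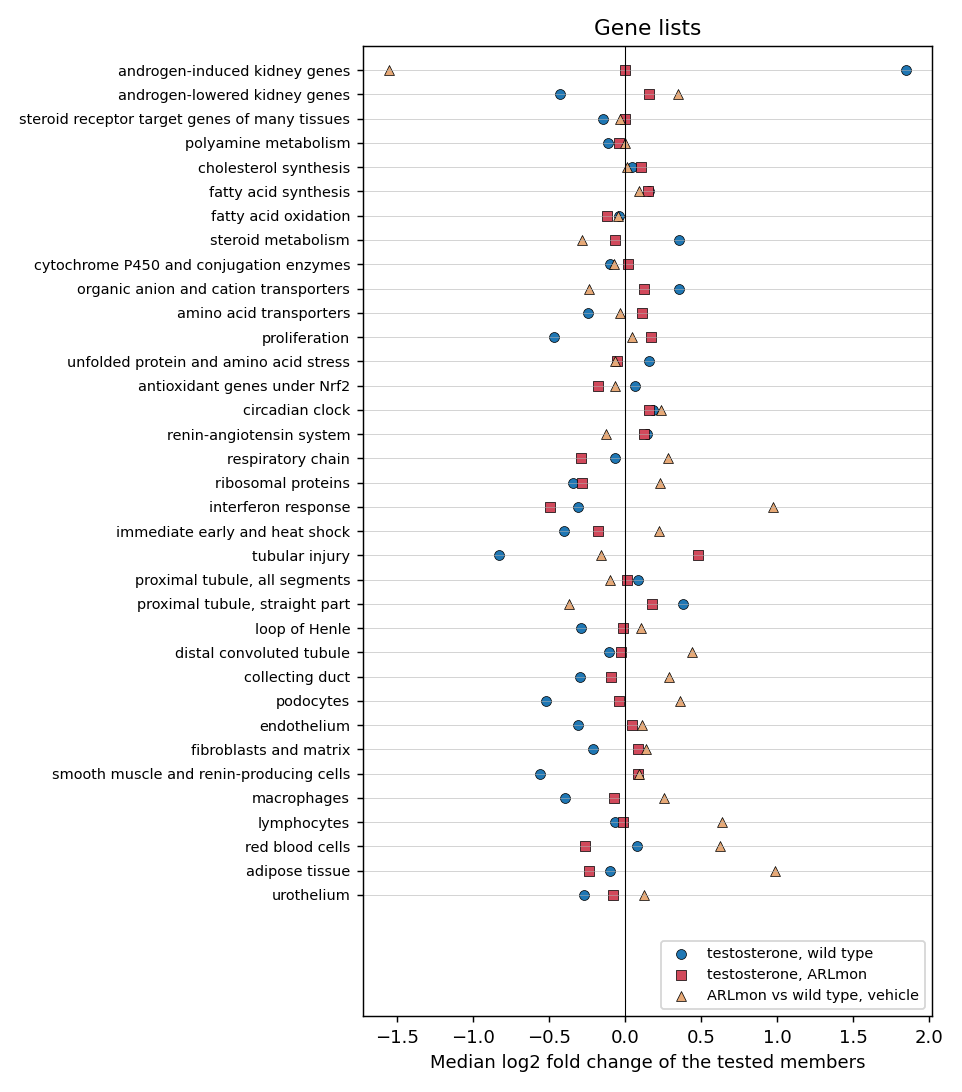
Median log2 change of each gene list in the wild type and ARLmon testosterone comparisons and in the vehicle comparison of genotypes, with 1 row per list and 1 marker per comparison. The androgen-induced list stands at 1.85 in wild type, 0.00 in ARLmon and -1.55 between vehicle groups.

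The next comparison asked what testosterone changes in ARLmon kidneys. Odc1 was at 202 ± 24.2 CPM with vehicle and 188 ± 26.8 with testosterone, a log2 difference of -0.10 with a 95% interval of -0.34 to 0.14 (edgeR adjusted p = 0.796). Kap was at 8184 ± 4642 and 6450.4 ± 1307 CPM, a log2 difference of -0.34 with an interval of -0.99 to 0.30 (adjusted p = 0.776), which turned to 0.02 without ARLmon vehicle library GC078618. Slco1a1 stood at 0.321 and 0.348 CPM, Prlr at 189 and 224, and Synpr had no reads in either ARLmon group. No gene of 15549 passed the edgeR test, where 813 had an unadjusted p below 0.05 against 777.45 expected, and the smallest adjusted p was 0.774. DESeq2 and limma-voom also called 0 genes, with 937 and 808 at an unadjusted p below 0.05. On counts simulated with the means, sizes and spread of these libraries, the same test recovered 80.6% of 2-fold and 92.4% of 4-fold changes.

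No member of any list passed the test over all genes in ARLmon. The 82 respiratory chain genes had a median log2 difference of -0.29 (camera adjusted p = 7.88e-23, and adjusted p = 0.703 with an estimated correlation) and the 78 ribosomal protein genes one of -0.28 (camera adjusted p = 5.97e-23, and adjusted p = 0.703 with an estimated correlation). The 26 interferon response genes had a median of -0.49, and 18 of them fell when adjusted over the list alone (camera adjusted p = 2.15e-15, and adjusted p = 0.655 with an estimated correlation). Fatty acid synthesis stood at 0.15 (camera adjusted p = 0.00941, and adjusted p = 0.703 with an estimated correlation) and fatty acid oxidation at -0.12 (camera adjusted p = 0.00941, and adjusted p = 0.842 with an estimated correlation). Antioxidant genes under Nrf2 stood at -0.17 (camera adjusted p = 0.008, and adjusted p = 0.703 with an estimated correlation), cholesterol synthesis at 0.11 (camera adjusted p = 0.0328, and adjusted p = 0.842 with an estimated correlation) and the straight part of the proximal tubule at 0.18 (camera adjusted p = 0.04, and adjusted p = 0.842 with an estimated correlation). No member of these lists other than the interferon genes passed when adjusted over the list alone. By camera 8 lists passed and 0 with an estimated correlation. The count was 5 without GC078617 and 13 without GC078618, both ARLmon vehicle libraries. Most of these lists also separated libraries of one group along the main axis of that spread, on which GC078604 and GC078618 lie farthest. Against random lists, respiratory chain and ribosomal protein genes lay at percentile 100 of it, antioxidant genes at 99.0, fatty acid oxidation at 97.7 and interferon response at 97.2, and the medians of these 5 were below 0. Cholesterol synthesis lay at 3.4, fatty acid synthesis at 4.25 and the straight part of the proximal tubule at 11, with medians above 0. With each library's score on that axis as a covariate 12 lists passed, these 8 among them, and so did 12 with these 8 without GC078604 and GC078618. With 1 library left out, the calls of 5 lists were lost: cholesterol synthesis without GC078604, GC078616, GC078617 or GC078619 (adjusted p up to 0.254, without GC078617), fatty acid synthesis without GC078617 (0.15), fatty acid oxidation without GC078613 or GC078619 (up to 0.0778, without GC078619), antioxidant genes without GC078621 (0.142) and the straight part of the proximal tubule without GC078604, GC078612, GC078615, GC078617, GC078620 or GC078621 (up to 0.359, without GC078621).

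Across the 2444 genes called in wild type, the ARLmon response had a slope of 0.0807 per unit of wild type response (Pearson r = 0.361 across genes, which are not independent replicates). The jackknife SE over libraries was 0.0588, and the slope fell to 0.0361 without ARLmon testosterone library GC078615. The median size of the log2 change was 0.59 in wild type and 0.12 in ARLmon, and 68.0% of the genes had the same sign in both. For 2205 of the genes the wild type value lay outside the 95% interval of the ARLmon value. That count leaves out the error of the wild type values, which were chosen by their own test. The test of the difference between the responses called 730 of the 2444. For simulated changes in wild type alone, that test recovered 12.3% at 1.5-fold, 68.7% at 2-fold and 87.9% at 4-fold. Genes it did not call may therefore still respond differently.

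**Figure D4:**
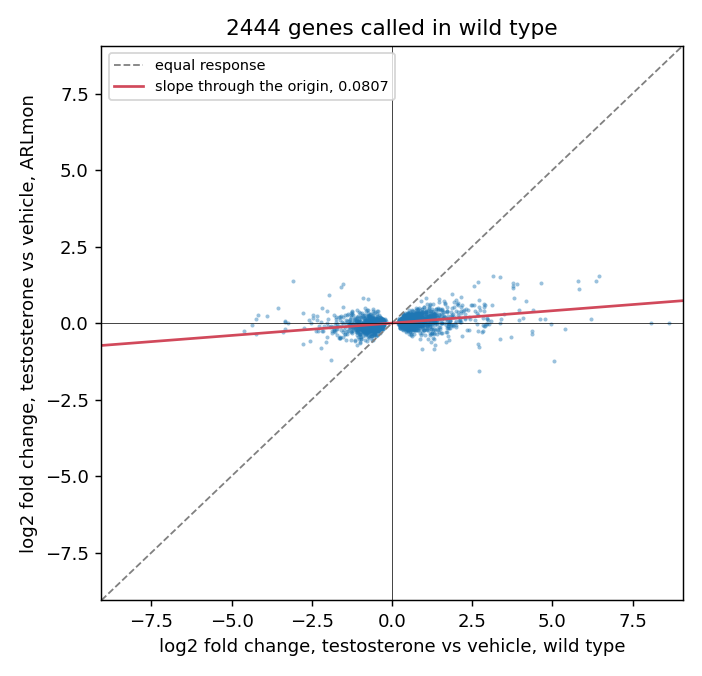
Log2 change with testosterone in ARLmon kidneys (vertical axis) against wild type kidneys (horizontal axis) for the 2444 genes called in wild type, with 1 point per gene and the fitted line through the origin. The line has a slope of 0.0807, and the points lie along the horizontal axis.

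The difference between the genotypes' responses was tested as an interaction. Odc1 differed by -2.97 ± 0.17 on the log2 scale (edgeR adjusted p = 2.69e-10) and Kap by -1.76 ± 0.44 (adjusted p = 0.0207), where negative values of genes that rose mark a smaller response in ARLmon. The largest negative values were those of Lipo2 (-6.27 ± 1.10), Slco1a1 (-6.06 ± 0.66), Ctxn3 (-5.58 ± 0.57), Rnf180 (-4.65 ± 0.62) and Ccl28 (-4.48 ± 0.67). The largest positive values, all of genes that fell in wild type, were those of Slc7a12 (4.46 ± 0.85), Fgb (4.39 ± 1.22), Ugt1a2 (4.32 ± 0.57), Prlr (4.13 ± 0.40) and Fgg (4.04 ± 0.94). Without GC078606 the values were 2.47 for Fgb and 2.24 for Fgg, and without GC078611 5.41 for Slc7a12 and 5.07 for Ugt1a2. Slc7a12 was at 3.62 and Ctxn3 at -6.38 without GC078615, Lipo2 at -4.98 without GC078619 and Fgb at 3.77 without GC078612. The call of Fgb was lost with limma-voom, at an adjusted p of 0.23, and without any one of GC078607 to GC078612, GC078614 or GC078617 to GC078620, with an adjusted p of up to 0.0872. In all 741 genes passed, 221 with a positive and 520 with a negative difference, and 47 of them are predicted or unnamed. Of these, 730 were also called in wild type, 513 as rising and 217 as falling, and all 741 had the smaller change in ARLmon. With library size as the only scaling, 67.8% of the differences were positive, against 29.8%, and the median of all genes was 0.20, against 0.02.

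Of the 20 androgen-induced genes, 15 had a smaller rise in ARLmon and none a larger one (17 and 1 adjusted over the list alone; camera adjusted p = 3.9e-27, and adjusted p = 2.15e-05 with an estimated correlation), as for Hsd17b11 (-3.00 ± 0.13), Acsm3 (-3.85 ± 0.34) and Nudt19 (-2.78 ± 0.27). Of 24 steroid metabolism genes, 6 differed, each with a negative value (8 negative and 1 positive adjusted over the list alone; camera adjusted p = 3.44e-05, and adjusted p = 0.0236 with an estimated correlation), as for Hsd11b1 (-2.92 ± 0.24) and Srd5a2 (-3.28 ± 0.46). Of 12 androgen-lowered genes, 4 differed, each with a positive value (5 positive and 0 negative adjusted over the list alone; camera adjusted p = 6.19e-05, and adjusted p = 0.0601 with an estimated correlation), including Kynu (3.39 ± 0.23) and Hao2 (2.74 ± 0.34). Of 27 amino acid transporter genes 6 differed, each with a positive value (6 positive and 0 negative adjusted over the list alone; camera adjusted p = 0.00195, and adjusted p = 0.266 with an estimated correlation), as for Slc7a8 (0.96 ± 0.13) and Slc3a2 (0.87 ± 0.15). By camera 12 lists passed, and 2 did with an estimated correlation, the androgen-induced and the steroid metabolism genes. The 8 lists not described had adjusted p between 0.203 and 0.778 with an estimated correlation.

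The vehicle groups were compared to ask how the genotypes differ without added testosterone. Slc7a13 was at 169.8 ± 64.9 CPM in wild type and 1.25 ± 0.184 in ARLmon vehicle kidneys, a log2 difference of -7.09 ± 0.42 (edgeR adjusted p = 2.16e-10). Slco1a1 differed by -5.94 ± 0.30, from 19.5 ± 3.14 to 0.321 ± 0.242 CPM (adjusted p = 1.96e-11). Ugt1a2 was higher in ARLmon, at 239.6 ± 61.0 against 5.06 ± 1.94 CPM (log2 5.57 ± 0.28, adjusted p = 1.96e-11). Also lower were Apoh (-7.42 ± 0.97), the cytochrome P450 gene Cyp2j13 (-6.70 ± 0.37) and the protease inhibitor gene Pzp (-6.56 ± 0.32). Also higher were the solute carrier genes Slc17a2 (3.97 ± 0.40) and Slc22a29 (2.44 ± 0.16), the efflux pump gene Abcc3 (3.14 ± 0.32) and Wfdc16 (2.66 ± 0.29). Without GC078606 the difference of Apoh was -6.18. Apoh overlaps the antisense gene Prkca and Pzp the antisense gene Gm10069, so their reads are uncertain.

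Odc1 differed by -0.03 ± 0.12 between the vehicle groups (adjusted p = 0.925), with the sign turned to 0.07 without GC078604 and to 0.03 without GC078620. Kap differed by -0.85 ± 0.31 (adjusted p = 0.137), and passed without ARLmon vehicle library GC078618, at -1.22 (adjusted p = 0.0156). In all 680 genes passed, 310 higher and 370 lower in ARLmon, 245 of them by at least 2-fold, and 55 are predicted or unnamed. DESeq2 called 989 genes, limma-voom 785 and the fit of the 10 libraries of the pair alone 330. The count was 413 without GC078605 and 1211 without GC078604, both wild type vehicle libraries. With library size as the only scaling 66.7% of the genes were higher, against 45.6%.

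Of the 20 androgen-induced genes, 13 were lower and 2 higher in ARLmon vehicle kidneys (15 and 2 adjusted over the list alone; camera adjusted p = 6.75e-26, and adjusted p = 2.91e-05 with an estimated correlation). Timd2 (-3.93 ± 0.18), Cyp4b1 (-3.74 ± 0.19) and Cyp2e1 (-2.62 ± 0.15) were lower, while Abcc4 (1.32 ± 0.17) and Aadat (1.55 ± 0.31) were higher. Of 46 cytochrome P450 and conjugation genes (12 also in another list), 16 were lower and 4 higher (18 and 9 adjusted over the list alone; camera adjusted p = 3.06e-05, and adjusted p = 0.134 with an estimated correlation), with Cyp2d9 (-2.81 ± 0.19) among the lower and the glutathione transferase gene Gsta4 (2.08 ± 0.21) among the higher. Of 24 steroid metabolism genes, 6 were lower and 2 higher (10 and 5 adjusted over the list alone; camera adjusted p = 0.000576, and adjusted p = 0.08 with an estimated correlation), with Cyp7b1 (-4.46 ± 0.30) lower and Hsd17b14 (1.59 ± 0.24) higher. Of 34 transporter genes, 9 were lower and 5 higher (12 and 6 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.453 with an estimated correlation), with Slco3a1 (-1.43 ± 0.14) lower and Abcc3 higher. ARLmon vehicle library GC078621 stood lowest for both lists. Without it the camera adjusted p was 0.00229 for steroid metabolism and 0.0594 for the transporters, whose call was also lost without GC078603 (0.0534) or GC078604 (0.0619). Of 10 markers of the straight part of the proximal tubule, 4 were lower (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 4.98e-07, and adjusted p = 0.134 with an estimated correlation), including Slc22a30 (-2.77 ± 0.31) and Atp11a (-1.14 ± 0.25).

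Interferon response genes were higher in ARLmon vehicle kidneys for 20 of 26 members and lower for none (24 adjusted over the list alone; camera adjusted p = 6.91e-22, and adjusted p = 0.08 with an estimated correlation), and no member is in another list. Gbp3 differed by 1.60 ± 0.24, Ifit1 by 1.72 ± 0.30, Irf7, a transcription factor of the interferon response, by 1.39 ± 0.25, and Ifit3 by 1.07 ± 0.19. Markers of immune cells moved with them. Of 14 macrophage genes 1 was higher (4 adjusted over the list alone; camera adjusted p = 0.00387, and adjusted p = 0.462 with an estimated correlation), and of 13 lymphocyte genes 1 (1 adjusted over the list alone; camera adjusted p = 0.00155, and adjusted p = 0.426 with an estimated correlation). The mean of both lists was higher by 0.50 on the log2 scale (two-sided exact permutation p = 0.0238).

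Of 10 distal convoluted tubule genes 2 were higher (4 adjusted over the list alone; camera adjusted p = 8.62e-05, and adjusted p = 0.225 with an estimated correlation), among them the calbindin gene Calb1 (0.85 ± 0.18). Of 16 collecting duct genes 3 were higher (7 adjusted over the list alone; camera adjusted p = 0.000255, and adjusted p = 0.424 with an estimated correlation), and of 10 podocyte markers 1 (7 adjusted over the list alone; camera adjusted p = 3.6e-05, and adjusted p = 0.218 with an estimated correlation). Of 11 adipose tissue markers 1 was higher (5 adjusted over the list alone; camera adjusted p = 0.000371, and adjusted p = 0.453 with an estimated correlation), and of 7 red blood cell genes 1, which is also a collecting duct gene (1 adjusted over the list alone; camera adjusted p = 0.00862, and adjusted p = 0.453 with an estimated correlation; adjusted p = 0.109 without GC078606). Cox7a1 (0.87 ± 0.19), a cytochrome oxidase subunit gene, was the 1 of 82 respiratory chain genes that was higher (1 adjusted over the list alone; camera adjusted p = 8.51e-13, and adjusted p = 0.453 with an estimated correlation), and of 78 ribosomal protein genes 1 was (0 adjusted over the list alone; camera adjusted p = 3.33e-07, and adjusted p = 0.672 with an estimated correlation). By camera 15 lists passed and 1 with an estimated correlation, the androgen-induced genes. Respiratory chain, ribosomal protein, macrophage, lymphocyte, red blood cell and adipose tissue genes lay at percentile 100 of the axis between libraries of one group. Its high end holds short transcripts. Collecting duct genes lay at 98.6 and interferon response genes at 97.2. Distal convoluted tubule genes, also higher here, lay at 2.2, and cytochrome P450 and conjugation genes, lower here, at 99.3. With the axis scores as a covariate 16 lists passed, these 15 among them.

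Under testosterone the genotypes differed in more genes. Odc1 was lower in ARLmon, with a difference of -3.00 ± 0.12 on the log2 scale (edgeR adjusted p = 1.24e-13) and so was Kap, with -2.61 ± 0.33 (adjusted p = 3.1e-06). Slco1a1 (-12.00 ± 0.32), Cyp2j13 (-9.23 ± 0.38), Pzp (-8.89 ± 0.31) and Slc7a13 (-8.43 ± 0.42) were among the most lowered. Cyp2b10, a cytochrome P450 gene, had 0 reads in ARLmon testosterone kidneys and averaged 26.7 ± 34.4 CPM in wild type, at least 682-fold lower against a floor of 3 reads over the group (at least 291-fold without GC078611, which alone had 87.8 CPM), and Synpr was at least 248-fold lower on that floor. Cntnap5a, with 1 read in ARLmon, had a wild type to ARLmon ratio of 808 (lower 95% counting limit 145), and Mpped1, with 2 reads, a ratio with a lower limit of 172. The most raised were Ugt1a2 (9.89 ± 0.42), Slc17a2 (5.95 ± 0.53), Prlr (5.41 ± 0.32), Slc7a12 (5.11 ± 0.68), Slc22a29 (5.10 ± 0.21), Ugt1a10 (4.42 ± 0.53), Gc (4.42 ± 0.37) and Kynu (4.06 ± 0.18). Slc7a12 was at 6.06 without GC078611 and 4.27 without GC078615, Ugt1a2 at 10.64 without GC078611 and Ugt1a10 at 5.34 without GC078610.

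In all 4842 genes passed, 2431 higher and 2411 lower in ARLmon, 1057 of them by at least 2-fold, and 366 are predicted or unnamed. With library size as the only scaling 82.4% of the genes were higher, against 50.2%, and the median of all genes was 0.28, against 0.04. Of the 20 androgen-induced genes 18 were lower and 1, Abcc4, higher (18 and 1 adjusted over the list alone; camera adjusted p = 1.08e-25, and adjusted p = 3.06e-05 with an estimated correlation), and of 24 steroid metabolism genes 13 were lower and 3 higher (14 and 5 adjusted over the list alone; camera adjusted p = 5.13e-05, and adjusted p = 0.0303 with an estimated correlation). Of 12 androgen-lowered genes 7 were higher and 2, Cyp2a4 and Slco1a6, lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.00214, and adjusted p = 0.202 with an estimated correlation). All 10 podocyte markers were higher, also when adjusted over the list alone (camera adjusted p = 3.05e-06, and adjusted p = 0.202 with an estimated correlation), with Podxl at 0.79 ± 0.10. Of 26 interferon response genes 17 were higher (22 adjusted over the list alone; camera adjusted p = 4.95e-06, and adjusted p = 0.505 with an estimated correlation), with Gbp3 at 1.84 ± 0.26. Of 10 smooth muscle and renin cell markers 9 were higher (9 adjusted over the list alone; camera adjusted p = 0.000962, and adjusted p = 0.221 with an estimated correlation), with Rgs5 at 0.71 ± 0.13, and of 14 macrophage genes 9 were higher and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 0.00681, and adjusted p = 0.505 with an estimated correlation). By camera 18 lists passed, and 2 did with an estimated correlation, the androgen-induced and the steroid metabolism genes. The 11 lists not described had adjusted p between 0.505 and 0.686 with an estimated correlation.

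ARLmon testosterone kidneys were also set beside wild type vehicle kidneys. Kap was lower, with a log2 difference of -1.20 ± 0.31 (edgeR adjusted p = 0.0387), a call lost without wild type vehicle library GC078604, at -0.81 (adjusted p = 0.134), and with the 10 libraries of the pair alone (adjusted p = 0.0612). It was also lost without any one of GC078609, GC078610, GC078612, GC078613, GC078614 or GC078616, with an adjusted p of up to 0.108. Odc1 differed by -0.13 ± 0.12 (adjusted p = 0.646). The most lowered genes were Apoh (-7.02 ± 0.92), Cyp2j13 (-6.10 ± 0.35), Pzp (-6.02 ± 0.30), Slc7a13 (-5.86 ± 0.39) and Slco1a1 (-5.80 ± 0.30), and the most raised Ugt1a2 (5.51 ± 0.28), Slc17a2 (4.44 ± 0.40), Abcc3 (3.40 ± 0.32), Slc22a29 (2.53 ± 0.16) and Wfdc16 (2.16 ± 0.29). Apoh was at -5.78 without GC078606. In all 471 genes passed, 195 higher and 276 lower, 191 of them by at least 2-fold, and 42 are predicted or unnamed. DESeq2 called 728 genes, limma-voom 531 and the fit of the 10 libraries of the pair alone 255. With library size as the only scaling 65.7% were higher, against 41.4%, and the median of all genes was 0.10, against 0.01. Of the 20 androgen-induced genes 15 were lower and 2 higher, also when adjusted over the list alone (camera adjusted p = 2.62e-30, and adjusted p = 1.04e-05 with an estimated correlation). By camera 18 lists passed, and 1 did with an estimated correlation, the androgen-induced genes. The 17 lists not described had adjusted p between 0.0539 and 0.574 with an estimated correlation.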

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

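The comparisons of the genotypes' responses were planned, and of the tests given here those of transcript length and of the tubule segments were chosen only after the result was seen. In a group of 5, a library stands apart where its gap to the nearest other library is over 0.71 of the group's range, which chance gives in about 1 group in 20. Among named genes this happened in 17 of 116 groups (5.8 expected) and among gene lists in 12 of 140 (7 expected). For the library total and the percentage of mitochondrial counts it happened in 1 of 8 groups (0.4 expected). The values below are that gap as a share of the range, on log2 CPM.

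In wild type vehicle kidneys, library GC078604 was highest for Kap (0.723) and Odc1 (0.712) and lowest for Ugt1a10 (0.839). Library GC078606 was highest for Fgb (0.737), Fgg (0.825), Kcnip2 (0.716), Gc (0.791) and the list of smooth muscle and renin-producing cells (0.848), and lowest for Cntnap5a (0.723). In wild type testosterone kidneys, GC078611 was highest for Cyp2b10 (0.736) and amino acid transporters (0.713) and lowest for proliferation (0.752), and GC078608 was lowest for cholesterol synthesis (0.729).

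In ARLmon vehicle kidneys, GC078621 was lowest for Prlr (0.773), Slc7a12 (0.779), steroid metabolism (0.747), organic anion and cation transporters (0.738), the renin-angiotensin system (0.734) and the loop of Henle (0.806). It was the only library of its group with reads of Mpped1 (1). GC078618 was lowest for fibroblasts and matrix (0.751) and GC078619 for smooth muscle and renin-producing cells (0.745). In ARLmon testosterone kidneys, GC078615 was highest for organic anion and cation transporters (0.789) and Ctxn3 (0.761) and alone had a read of Cntnap5a (1). GC078612 was highest for tubular injury (0.884), Fgb (0.753) and Fgg (0.724) and lowest for Lipo2 (0.724) and for the percentage of mitochondrial counts (0.917), at 6.86% against 9.80% in the next library. Its level of Havcr1, a marker of injured proximal tubule, was 105.3 CPM.

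The test of the difference between the genotypes' responses singled out 741 genes and, among named genes, Kap (-1.76), Odc1 (-2.97), Lipo2 (-6.27), Slco1a1 (-6.06), Ctxn3 (-5.58), Rnf180 (-4.65), Ccl28 (-4.48), Slc7a12 (4.46), Fgb (4.39), Ugt1a2 (4.32), Prlr (4.13) and Fgg (4.04). Without GC078606 Fgb was at 2.47 and Fgg at 2.24, without GC078619 Lipo2 was at -4.98, and without GC078615 Slc7a12 was at 3.62. Chance can be excluded for the count, since 2 of 100 splits of the libraries, the real one included, gave as many genes, though the highest other gave 2654. The count for the interaction was 579 without GC078610 and 967 without GC078604, so no single library decides it.

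Libraries of one group differed along a main axis that held 30.4% of the variance within groups, with GC078604 and GC078618 farthest. Genes with short transcripts lay at its high end (Spearman -0.547 across 14799 genes between loading and exon length, which are not independent replicates, with median exon lengths of 1243 bases in the top 500 genes and 7412.5 in the bottom 500), which may point to RNA integrity or library preparation. A different share of proximal tubule alone would move the other segments alike. The loop of Henle (percentile 13.3 of random lists), distal convoluted tubule (2.2) and collecting duct (98.6) moved apart (permutation p = 0.0213, members shuffled between the lists). The shuffles treat genes as independent and do not account for transcript length, so this does not decide it. The planned comparison of the proximal tubule (34.0) with these 3 pooled decides nothing either, since they moved apart. A different share of proximal tubule stays open, and so, untested, does one of collecting duct or of another part of the kidney. Library size cannot be told apart from this (Pearson -0.368, permutation p = 0.225; Spearman -0.436, permutation p = 0.0827; Pearson -0.552 without the 2 farthest libraries; n = 20), because with 20 libraries the relation neither passed nor was excluded. Apart from the share of tubule no biological explanation was tested, and the axis also carried genes of the respiratory chain, ribosomal proteins, tubular injury, macrophages, lymphocytes, red blood cells and adipose tissue, all at percentile 100.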

How the results depend on the processing

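No paired analysis was possible because the columns carry library codes, not the labels' replicate numbers, so the planned fits with a replicate block were not run. The fits without 2 libraries, with the main axis of variation within groups as a covariate and of limma on the deposited log2 values were chosen after seeing the data. For ARLmon testosterone against vehicle no table of the pair was used, so that alternative was not run either. With RLE factors, the stricter filter and no filter the 6 counts of genes stayed within 1.5 times their value, and the ARLmon count was 0 in every setting run. Requiring a log2 change of at least 1 left 522 genes in wild type, 245 under vehicle, 1057 under testosterone, 191 for ARLmon testosterone against wild type vehicle and 326 for the interaction, by construction. The axis covariate gave 3777 (wild type), 1775 (vehicle), 1311 (ARLmon testosterone against wild type vehicle) and 1990 (interaction) genes. The deposited log2 values gave 3710 genes in wild type and 7528 between genotypes under testosterone. With the 10 libraries of the pair alone, or the authors' table of the pair, 330 genes passed under vehicle and 255 for ARLmon testosterone against wild type vehicle, where fewer samples enter the fit, and DESeq2 gave 728 for the latter. The cause was not tested for the other changes.

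With an estimated correlation 1 list passed in wild type, 0 in ARLmon, 1 under vehicle, 2 under testosterone and 2 for the interaction, and fry called 12 in wild type, 0 in ARLmon, 9 under vehicle, 24 under testosterone and 7 for the interaction. Of 68 calls of single lists 6 held with an estimated correlation and 65 with the axis covariate. Leaving out 1 library gave 413 (without GC078605) to 1211 (without GC078604) genes under vehicle and 5 (without GC078617) to 13 (without GC078618) lists in ARLmon. DESeq2 gave no adjusted p for 4 named values.

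With the deposited log2 values Slc22a29 turned to 0.65 in wild type and -0.54 in the interaction, and Slc22a27 to -0.13 between genotypes under testosterone. Kap in ARLmon turned to 0.0235 without GC078604 and GC078618 and ran from -0.51 to 0.0235 (without GC078618) with 1 library left out. Odc1 under vehicle turned to 0.0402 with library size alone, 0.0516 without GC078604 and GC078618 and 0.0499 with the deposited log2 values, and ran from -0.0872 to 0.0714 (without GC078604) with 1 library left out. Depth limits genes near the floor of 3 reads over a group, such as Synpr, to bounds.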

Other observations

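The axis covariate was chosen after the data were seen, and its test on the vehicle comparison only after the result was seen. In wild type kidneys given testosterone, 2 of 14 polyamine genes rose and none fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.364). Of 30 fatty acid oxidation genes 7 rose and 8 fell (9 and 8 adjusted over the list alone; camera adjusted p = 0.889), and of 46 cytochrome P450 and conjugation genes 15 rose and 11 fell (15 and 13 adjusted over the list alone; camera adjusted p = 0.257). Of 24 cholesterol synthesis genes 5 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.257), and of 18 general steroid receptor targets 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.719).

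The clock genes Dbp and Arntl differed between libraries of one group. Dbp, which peaks late in the day, was at 3.56 and 3.07 CPM in wild type vehicle libraries GC078605 and GC078606 and at 113.7 in GC078604 of that group, while Arntl, which runs opposite to it, was at 36.8, 34.0 and 5.38. Wild type testosterone library GC078611 had 7.63 CPM of Dbp and 26.8 of Arntl, ARLmon vehicle library GC078620 had 23.1 and 27.8, and ARLmon testosterone library GC078614 had 19.7 and 25.5, each the lowest Dbp and highest Arntl of its group. None of 18 circadian clock genes changed with testosterone in wild type, also when adjusted over the list alone (camera adjusted p = 0.257). Cyp2b10 was at 87.8 CPM in GC078611 and 19.8 in GC078606. Adrenal gland genes reached at most 19.3 CPM (Hsd3b1) and 12.3 CPM (Star) in any library.

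Each count of genes was set beside 100 splits of the libraries. Chance can be excluded for wild type testosterone (1 of 100 splits as large, the real one with 2444 genes; highest other 219), for genotypes under testosterone (1 of 100; 4842 and 1304) and for ARLmon testosterone against wild type vehicle (2 of 100; 471 and 532). It cannot be excluded for genotypes under vehicle (5 of 100; 680 and 4260). The split with 4260 genes points to a structure of the samples. For testosterone in ARLmon the real count was 0, so all 100 of 100 splits gave at least as many (highest other 0) and the splits say nothing about chance. Chance cannot be excluded either for the counts of lists in wild type (17 of 100; 15 and 19), in ARLmon (74 of 100; 8 and 22), under vehicle (25 of 100; 15 and 22), under testosterone (9 of 100; 18 and 22) and for the interaction (37 of 100; 12 and 20), or for the slope (7 of 100; 0.0807 and 0.0958).

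The difference between ARLmon and wild type under vehicle ran against the wild type testosterone response: 77.9% of the 2444 genes called in wild type had the opposite sign, and of genes lower in ARLmon 227 rose with testosterone (34.6 if independent). The shared wild type vehicle libraries push towards the same sign, with 37.3% opposite in simulations, and with those libraries divided between the comparisons the share was at least 77.1%, which argues against them. With the axis covariate 100% of the called genes stayed called. That covariate is drawn from the same libraries and lowers the spread within groups, which favours calls, so differences along the main axis are not decided by it. Androgen action left in wild type vehicle kidneys 4 days into the experiment stays open. Of the vehicle calls 47.6% (7.99% if independent) were called with the opposite sign in wild type, short of the share set beforehand for this explanation. That share restates the pattern over another set of genes, so it does not decide the cause. A difference that arose before orchidectomy cannot be told apart from such androgen action, since no intact mice were measured.

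Interferon response genes were higher in ARLmon vehicle kidneys (mean score difference 0.93 on the log2 scale, exact permutation p = 0.00794, the smallest that 5 libraries against 5 can give). A single library is argued against, as at least 15 of the 20 called members passed with any 1 library left out. With the axis covariate 24 passed, but that covariate lowers the spread within groups, so differences along the main axis are not decided by it. More immune cells in ARLmon vehicle kidneys may be part of it, as 6 members passed with the macrophage and lymphocyte mean as a covariate and the median member difference went from 0.97 (SE 0.230) to 0.64 (SE 0.237), so the call ended for most members by a smaller difference. Cage, litter and infection stay open, untested, and genotype stays among the open explanations.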
